A study of Oryza sativa with 12 samples.

How the data were processed

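RNA was measured in roots of 7-day-old rice seedlings (Oryza sativa, cultivar XS134) in 12 libraries. Per the labels, they came from wild type plants and from RNAi line 1 against OsPEP1, each treated with ethanol or with 1 µM PEP1, with 3 libraries in each of the 4 groups. PEP1 is the exogenous signal named by the labels, which give neither its solvent nor the duration of the treatment. Per the labels' protocols, total RNA was taken with Trizol from frozen root tissue and 1 µg went into Illumina TruSeq RNA libraries. The labels do not say that the 3 libraries of a group came from separate cultures, so every p-value measures only the spread between these samples, which may be technical.

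The authors deposited 1 table of raw read counts per gene, whole numbers that were not normalized, for 57265 features. Of these, 55801 carry a rice locus ID of the form LOC_Os, 1279 carry a serial number outside that scheme (such as Novel00347), and 185 carry an fgenesh ID. In 21168 features no library had a count. Every column of the table was matched to a sample by its title. The aligner, the genome build, the annotation, the counting tool and the use of strand are not given in the sources used here. Reads from overlapping genes, from antisense partners and from near-identical copies therefore could have been divided or merged in the counts, and values of such genes are uncertain. No reference genome was used here.

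Total counts per library ranged from 15368736 to 21317008. A gene with 3 counts, the upper limit that a count of 0 allows, had 0.141 CPM (counts scaled to the library total) in the deepest library and 0.195 CPM in the shallowest. These floors cover counting error only. No pair of libraries within a group was a duplicate, since the chi-square per degree of freedom over genes was 15.0 or more in every pair.

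Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. All 12 libraries entered 1 fit with the 4 groups and no other term, with TMM factors and the default filter on low counts, which kept 25602 genes. The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the genes tested, and a gene passed at an adjusted p below 0.05. Standard errors (SE) of log2 changes are the absolute change divided by the square root of the F statistic. The fit gave 5 results: PEP1 against ethanol in the wild type, the same in the RNAi line, the RNAi line against the wild type under ethanol, the same under PEP1, and the interaction, that is, the difference between the PEP1 changes of the genotypes. CPM values are means of the TMM-scaled libraries with their SD. Where every library of a group was at 0, the fold was computed against 3 counts over the group and is a lower bound. The common biological coefficient of variation was 0.313.

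The table does not pair locus IDs with gene names, and none of its locus IDs matched the NCBI RefSeq gene table of assembly ASM3414082v1, which lists 39387 genes, so 0 IDs received a name from a table. The gene symbols printed here come from locus and symbol pairs written by hand from general knowledge of rice genes. They are not the authors' annotation, and their reliability is below that of a name matched by ID. Of these pairs, 46 were written before the data were examined and 286 afterwards. A pair was used as a name only where the RefSeq table lists the symbol on the chromosome in the locus ID and at a relative position within 0.03 of the locus. That held for 31 of the first and 210 of the second set. Among 231 neighbouring pairs along the chromosomes, 1 was out of order. This check finds gross errors in a pair, but it cannot tell neighbouring copies of a gene family apart. Locus IDs are printed with the symbols, and the remaining loci of the first set are used by ID or in counts only.

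Gene lists and their subjects were chosen before the data were examined, as were the comparisons, the tests, the alternatives and the rule for named genes. They had been written as patterns for gene descriptions. Because no descriptions came with the genes, those lists that held no locus could not be tested as fixed lists. In the text, a fixed list holds the loci written beforehand, and an extended list holds the named loci of that subject from both sets. Several extended lists hold only loci written after the data were examined. Among them are the cellulose synthase, phenylpropanoid, antioxidant, chaperone, cytokinin, gibberellin, early auxin response, clock and shoot marker lists. Loci added later are not independent evidence. Lists with at least 5 tested loci were tested with camera at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. Counts of passing loci are given over all genes tested and, where stated, adjusted over the list alone.

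The rule for named genes took, with no descriptions at hand, the 2 features with the largest rise and the 2 with the largest fall per comparison among those past the threshold with 2 CPM or more in the higher group and groups that did not overlap. To these it added the 2 members with the smallest p of each list with at least 2 members past the threshold, for at most 8 lists. Loci of the fixed lists were also followed in every comparison. Every other gene named here was singled out after its values had been seen. OsPEP1 itself is named neither in the counts nor in the reference table, so the level of the targeted gene was not analysed here and the labels of the RNAi line were not checked by it.

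The alternatives were RLE factors, library totals alone, no filter, a filter at 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with quality weights, the replicate number as a block, fits of only the groups compared, a minimum change of 2-fold, and each library left out in turn. An alternative without 3 libraries that stood apart (wild type ethanol replicate 1, RNAi ethanol replicate 2 and RNAi PEP1 replicate 2) was added after seeing the data. These libraries were picked without a set cut-off. Wild type PEP1 replicate 2 was kept, with log2 CPM correlations of 0.963 and 0.949 within its group. For RNAi ethanol replicate 2 they were 0.955 and 0.973. In the text, a call lost in a number of alternatives no longer passed in those. A division of the RNAi ethanol libraries between the comparisons of the reversal, with 1 library in one and the other libraries in the other, was also added after seeing the data. Other scaling moved the median log2 change of all genes by 0.064 or less.

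The fit was tested on simulated counts with known changes in 200 genes. At a 4-fold change it recovered 62% of changed genes for PEP1 in the wild type, 63% for PEP1 in the RNAi line, 56% and 55% for the genotypes under ethanol and PEP1, and 22% for the interaction. At a 2-fold change these shares were 26%, 17%, 18%, 19% and 1%. At that setting small changes were therefore often missed, most of all in the interaction. Where many more genes pass, as the 3934 for PEP1 in the RNAi line, the adjusted threshold is less strict. The shares can be too low for such a comparison. False calls numbered 1 to 4 genes per comparison. Camera at a correlation of 0.01 gave a list of unchanged genes an unadjusted p of 0.0117 for PEP1 in the RNAi line. For the other comparisons its p for such a list was 0.224 or more. Figures were drawn with matplotlib 3.10.9.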

Results

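The transcript response to added PEP1 was measured in roots of wild type rice and of an RNAi line against OsPEP1. Wild type ethanol, wild type PEP1, RNAi ethanol and RNAi PEP1 were each represented by 3 libraries. Total counts were 17005866, 17313260 and 15971937 in wild type ethanol, 20446200, 15368736 and 21158220 in wild type PEP1, 18751248, 18367960 and 16132215 in RNAi ethanol, and 21317008, 20134329 and 20220875 in RNAi PEP1. On the first principal component (40.1% of the variance) the RNAi PEP1 libraries lay below the RNAi ethanol libraries, and on the second (28.4%) the genotypes separated. In the wild type, ethanol replicate 1 (-7.59 on the first component) lay below PEP1 replicate 2 (0.58), and both lay between the remaining ethanol and PEP1 libraries.

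The first comparison asked how wild type roots responded to PEP1. Genes of iron uptake fell, and their list had the lowest median change of the fixed lists. LOC_Os07g15460 (NRAMP1, a metal transporter of the extended list, not of the fixed one) went from 1332 ± 148 CPM under ethanol to 32.0 ± 12.7 CPM under PEP1 (mean ± SD, n = 3 each). LOC_Os03g19420 (NAS2) and LOC_Os03g19427 (NAS1), which encode nicotianamine synthases of the phytosiderophore pathway, went from 2474 ± 512 to 76.1 ± 47.6 CPM and from 1805 ± 471 to 52.3 ± 32.5 CPM. LOC_Os03g46454 (IRT2, an iron transporter) went from 95.7 ± 23.1 to 0.834 ± 0.748 CPM, and LOC_Os02g43370 (YSL2, a transporter of metal chelates) from 1363 ± 201 to 40.1 ± 20.4 CPM.

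Of the 12 loci in the fixed iron list, 10 fell in the wild type, and 12 did when adjusted over the list alone, with a median log2 change of -4.52. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, YSL2 fell by 5.09 ± 0.39 on the log2 scale (SE, adjusted p = 6.55e-05) and IRT2 by 6.80 ± 0.54 (adjusted p = 7.35e-05). NAS1, NAS2, LOC_Os02g20360 (NAAT1, nicotianamine aminotransferase), LOC_Os02g43410 (YSL15, an iron phytosiderophore transporter) and LOC_Os03g26210 (IRO3, a bHLH transcription factor) also fell. The passing criterion was missed by LOC_Os03g46470 (IRT1; log2 change -2.63 ± 0.80, edgeR adjusted p = 0.0932) and LOC_Os07g48980 (NAS3; -0.37 ± 0.16, edgeR adjusted p = 0.240). The list moved down in camera (adjusted p = 2.52e-49), and it did so with an estimated correlation (adjusted p = 0.00147). In the extended iron list, 8 of 21 loci fell, NRAMP1 fell by 5.38 ± 0.35 (edgeR adjusted p = 2.57e-05), and the camera adjusted p was 0.0248 with an estimated correlation. NAS1 and NAS2 are neighbouring, closely similar copies, so reads can have been divided between them.

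**Figure D1:**
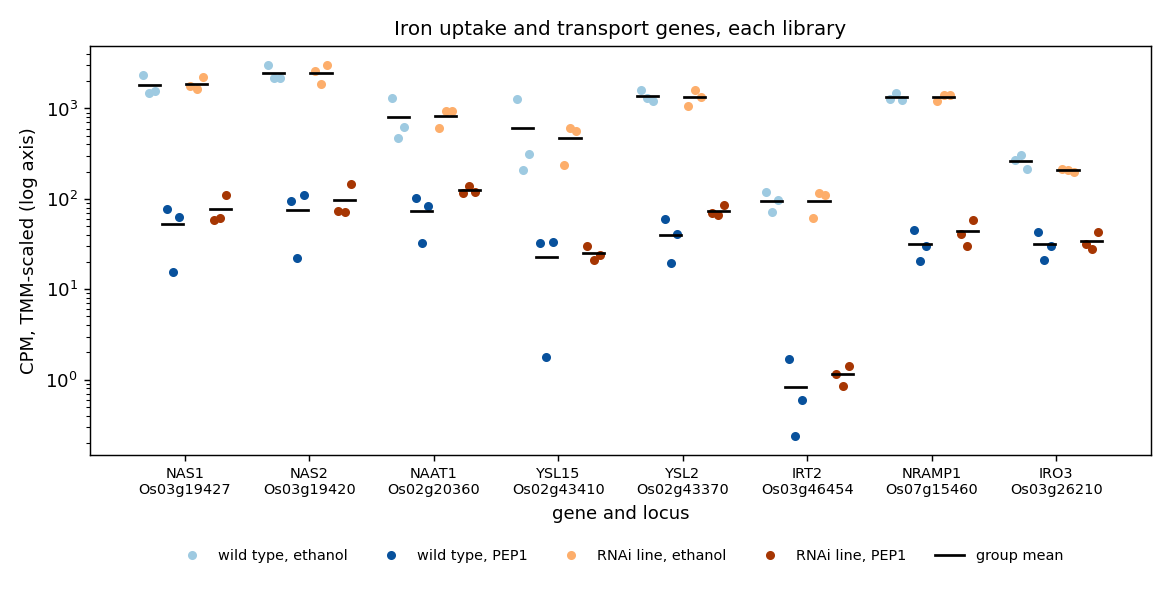
CPM (log axis) of 8 iron loci in each of the 12 libraries, by genotype and treatment; points are libraries and bars are group means of 3 libraries. In both genotypes every PEP1 library lies below every ethanol library for NRAMP1, whose means were 1332 and 32.0 CPM in the wild type.

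Phosphate starvation genes also fell in PEP1-treated wild type roots, by less. Of the 7 loci of the fixed list 4 fell, and 5 did when adjusted over the list alone (camera with an estimated correlation, adjusted p = 0.0279). LOC_Os06g40120 (SPX1, a phosphate sensor protein) went from 35.9 ± 7.55 to 18.3 ± 2.39 CPM, and LOC_Os08g45000 (PT6, a phosphate transporter) from 6.25 ± 1.45 to 0.477 ± 0.125 CPM. Of the 11 loci of the extended list 4 fell, among them LOC_Os03g29250 (SPX5), by 2.18 ± 0.27 (SE) on the log2 scale. The extended list's call was lost with an estimated correlation (camera adjusted p = 0.335).

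By number of rising loci, the aquaporin list came first among the lists in the wild type. Of 21 loci in the extended list, 9 rose and 1 fell in the wild type, and 14 rose and 1 fell when adjusted over the list alone. Without the 3 libraries that stood apart 11 rose, a smaller share than the 8 of 11 diterpenoid loci in that fit. LOC_Os01g74450 (TIP1-2, a tonoplast aquaporin) went from 265 ± 34.9 to 1316 ± 61.8 CPM, a log2 change of 2.31 ± 0.19 (SE, edgeR adjusted p = 7.81e-05). The plasma membrane aquaporins LOC_Os07g26660 (PIP2-5) and LOC_Os04g44060 (PIP2-3) rose from 134 ± 28.8 to 665 ± 118 CPM and from 903 ± 55.6 to 2512 ± 112 CPM, whereas LOC_Os04g16450 (PIP2-6) fell from 239 ± 39.2 to 114 ± 1.33 CPM. The silicon transporters LOC_Os02g51110 (Lsi1, itself of the aquaporin family) and LOC_Os03g01700 (Lsi2, an efflux transporter) rose by 1.62 ± 0.33 and 2.23 ± 0.41 on the log2 scale. Lsi2 is no aquaporin, but the extended list holds it, so the counts and the camera test of the list include it. Camera gave an adjusted p of 2.48e-13 for the aquaporins, and this call was lost with an estimated correlation (adjusted p = 0.0919). Only Lsi1 in the list was written before the data were examined, so the list is not independent evidence.

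**Figure D2:**
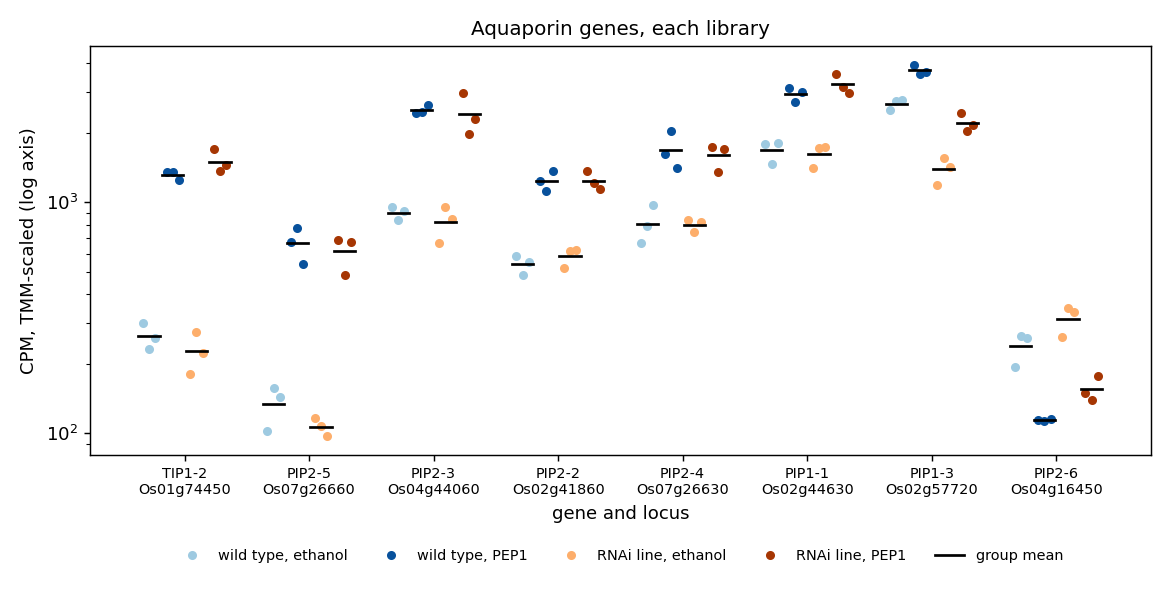
CPM (log axis) of 8 aquaporin loci in each of the 12 libraries, by genotype and treatment; points are libraries and bars are group means of 3 libraries. TIP1-2 rose in the wild type from a mean of 265 to 1316 CPM, and PIP2-6 is the locus that fell.

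Nitrogen, cell wall and hormone genes gave smaller counts in the wild type. None of the 7 loci of the fixed nitrogen list passed in edgeR over all genes, and 1 fell when adjusted over the list alone. Of 11 loci in the extended nitrogen list 3 fell, LOC_Os08g36480 (NIA1, nitrate reductase; from 164 ± 111 to 14.3 ± 2.35 CPM), LOC_Os02g50240 (GLN1;1) and LOC_Os04g56400 (GLN2), both glutamine synthetases (GLN2's call was lost in 9 of 21 alternatives). That list's camera call (adjusted p = 0.0125) was lost with an estimated correlation (adjusted p = 0.540). The nitrate transport genes LOC_Os02g02170 (NRT2.1), LOC_Os02g02190 (NRT2.2) and LOC_Os02g38230 (NAR2.1) had 202, 204 and 1225 CPM in wild type ethanol replicate 1, against at most 3.86, 9.02 and 60.4 CPM in the other libraries of that group. Of 9 cellulose synthase loci 1 fell, LOC_Os07g24190 (CESA3), and 5 fell when adjusted over the list alone (camera with an estimated correlation, adjusted p = 0.456). Without the 3 libraries that stood apart 4 fell, as many as in the RNAi line, and CESA3's call was lost in 7 of 21 alternatives. Of 5 phenylpropanoid loci 2 fell, LOC_Os06g44620 (4CL4) and LOC_Os02g08100 (4CL3), both 4-coumarate:CoA ligases (camera with an estimated correlation, adjusted p = 0.456).

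Among defence and stress lists in the wild type, 1 of 5 WRKY transcription factors rose, LOC_Os01g61080 (WRKY24), by 1.82 ± 0.44 (SE) on the log2 scale (list with an estimated correlation, camera adjusted p = 0.335). LOC_Os05g25770, the only WRKY locus fixed beforehand, rose too, by 1.19. WRKY24's call was lost in 9 of 21 alternatives, and without the 3 libraries that stood apart 3 of the 5 rose (median log2 change 2.36) against 4 in the RNAi line (2.44). Of 11 jasmonate loci 1 rose, LOC_Os06g11290 (OPR1, an oxophytodienoate reductase), and 1 fell, LOC_Os03g32314 (AOC, allene oxide cyclase), whose call was lost in 11 of 21 alternatives. Of 11 diterpenoid loci none rose and 1 fell, LOC_Os02g17780 (CPS1, an enzyme of gibberellin precursor synthesis), from 15.1 ± 6.88 to 0.753 ± 0.255 CPM; 0 of the 4 fixed phytoalexin loci passed in edgeR, and 1 rose when adjusted over the list alone. Without the 3 libraries that stood apart, 8 of the 11 rose and 3 fell (median log2 change 2.87), so the counts for this list depend on those libraries. Of 7 antioxidant loci 1 rose, LOC_Os03g17690 (APX1, ascorbate peroxidase), from 277 ± 25.0 to 704 ± 45.9 CPM (list with an estimated correlation, camera adjusted p = 0.456). Of 5 chaperone loci of the endoplasmic reticulum 1 rose, and 0 did without the 3 libraries in edgeR (estimated correlation, camera adjusted p = 0.467).

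Across all genes, 1330 passed in the wild type (650 higher, 680 lower under PEP1), of which 946 changed at least 2-fold. The largest rises were in LOC_Os08g25990, at least 50.6-fold higher against no reads under ethanol (a call lost in 10 of 20 alternatives), and Novel00457, at least 46.8-fold higher. The largest falls were in LOC_Os09g07230, at least 99.3-fold lower, and LOC_Os09g07180, from 13.5 ± 5.04 to 0.0328 ± 0.0284 CPM. Single libraries moved the count of passing genes, to 2942 without wild type ethanol replicate 1, 807 without ethanol replicate 2, 731 without ethanol replicate 3, 571 without PEP1 replicate 1 and 593 without PEP1 replicate 3. Without the 3 libraries that stood apart it was 2882, and with limma-voom it was 7427.

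The second comparison asked how roots of the RNAi line responded to PEP1. The iron genes fell there as well. NRAMP1 (LOC_Os07g15460, extended list) went from 1339 ± 109 to 43.6 ± 14.5 CPM (mean ± SD, n = 3 each), NAS2 (LOC_Os03g19420) from 2495 ± 577 to 97.4 ± 42.2 CPM, and IRT2 (LOC_Os03g46454) from 95.9 ± 30.4 to 1.14 ± 0.272 CPM. Of the 12 fixed loci 11 fell, with a median log2 change of -3.91; adjusted over the list alone, 11 fell and 1 rose. Camera gave an adjusted p of 0.0197 with an estimated correlation. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment IRT1 (LOC_Os03g46470) fell by 3.03 ± 0.81 on the log2 scale (SE, adjusted p = 0.0324), a call lost in 7 of 21 alternatives. Of the 21 loci of the extended list 9 fell, and NRAMP1 fell by 4.94 ± 0.34 (edgeR adjusted p = 4.34e-05). Camera called that list down, a call that was lost with an estimated correlation (camera adjusted p = 0.0979).

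Phosphate, aquaporin and cell wall genes of the RNAi line changed in these ways. Of 7 fixed phosphate loci 5 fell, among them SPX1 (LOC_Os06g40120), from 58.8 ± 8.41 to 14.4 ± 2.60 CPM, PT6 (LOC_Os08g45000) and LOC_Os02g10780 (SPX2, a call lost in 10 of 21 alternatives), and camera with an estimated correlation gave an adjusted p of 0.0289. In the extended list of 11, 5 fell, among them SPX5 (LOC_Os03g29250), from 26.4 ± 8.79 to 2.59 ± 0.0212 CPM (estimated correlation, camera adjusted p = 0.298). Of the 21 loci of the aquaporin list, Lsi2 included, 12 rose and 1 fell, and 15 rose and 1 fell when adjusted over the list alone. TIP1-2 (LOC_Os01g74450) went from 226 ± 47.1 to 1502 ± 173 CPM and PIP2-5 (LOC_Os07g26660) from 107 ± 9.37 to 615 ± 111 CPM, while PIP2-6 (LOC_Os04g16450) fell; the list's call was lost with an estimated correlation (camera adjusted p = 0.103). Lsi1 (LOC_Os02g51110) changed by 0.65 ± 0.32 in log2, with an edgeR adjusted p of 0.181. Of 9 cellulose synthases 4 fell, LOC_Os07g24190 (CESA3) and the secondary wall members LOC_Os01g54620 (CESA4), LOC_Os10g32980 (CESA7) and LOC_Os09g25490 (CESA9), the last from 212 ± 90.3 to 63.8 ± 38.5 CPM (estimated correlation, camera adjusted p = 0.593).

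Jasmonate and WRKY genes rose in the RNAi line. Of 11 jasmonate loci 9 rose and 1 fell, and without the 3 libraries that stood apart 6 rose and 0 fell in edgeR. OPR1 (LOC_Os06g11290) went from 3.56 ± 0.855 to 16.4 ± 2.60 CPM, LOC_Os10g25290 (TIFY11D, a JAZ repressor of jasmonate signalling) from 6.17 ± 2.69 to 29.5 ± 8.29 CPM, and LOC_Os03g55800 (AOS1, allene oxide synthase) from 27.5 ± 5.60 to 58.7 ± 6.56 CPM. All 5 WRKY loci of the extended list rose, among them WRKY24 (LOC_Os01g61080), from 8.06 ± 3.76 to 59.5 ± 21.3 CPM, LOC_Os02g08440 (WRKY71), from 47.5 ± 14.7 to 125 ± 27.0 CPM, and LOC_Os09g25060 (WRKY76), from 1.55 ± 0.749 to 28.8 ± 8.12 CPM; LOC_Os05g25770 rose by 1.69 on the log2 scale. Camera's call on each list was lost with an estimated correlation (adjusted p = 0.0979 for both). The 3 shoot markers moved the same way, with CAB2R (LOC_Os01g41710) changed by 3.86 ± 1.51 as their median, and though none passed in edgeR with all libraries or without the 3, a difference in tissue was not excluded for this rise.

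**Figure D3:**
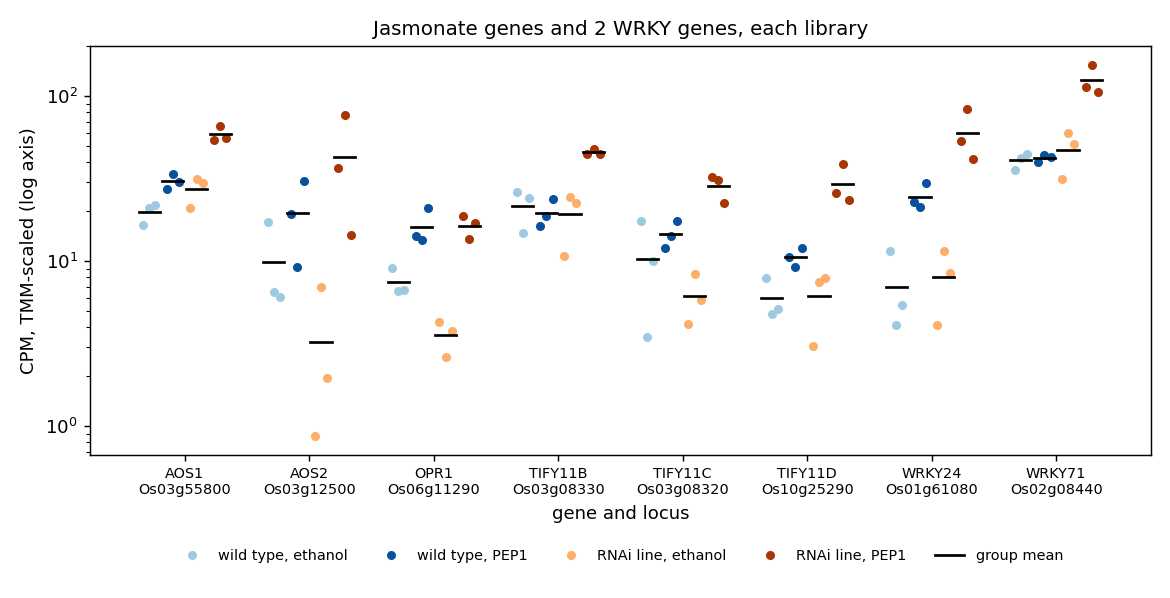
CPM (log axis) of 6 jasmonate and 2 WRKY loci in each of the 12 libraries, by genotype and treatment; points are libraries and bars are group means of 3 libraries. WRKY71 had means of 40.8 and 42.1 CPM in the wild type and 47.5 and 125 CPM in the RNAi line, under ethanol and PEP1.

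Diterpenoid genes moved with single libraries of the RNAi line. Of 11 loci 3 rose, LOC_Os04g10060 (KSL4), LOC_Os02g36070 (CYP76M8) and LOC_Os04g10160 (CYP99A2), all of phytoalexin synthesis (CYP99A2's call was lost in 8 of 21 alternatives), and 3 fell, among them CPS1 (LOC_Os02g17780) and LOC_Os04g52230 (KS1A), which act in gibberellin synthesis; of the 4 fixed loci, KSL4 rose. LOC_Os02g36140 (KSL7) had 63.7 CPM in RNAi ethanol replicate 2 and 287 CPM in RNAi PEP1 replicate 2 against at most 6.03 CPM in the other RNAi libraries, and LOC_Os02g36210 (CPS2) had 73.1 and 308 CPM in those libraries against at most 2.38. Without the 3 libraries that stood apart, 8 of the 11 loci rose and 2 fell (median log2 change 3.98). The libraries with the high KSL7 and CPS2 values are among those left out, so this count is no separate evidence of a rise. The shoot markers LOC_Os01g41710 (CAB2R), LOC_Os09g17740 (CAB1R) and LOC_Os11g47970 (RCA) also had their highest values, 228, 388 and 128 CPM, in RNAi PEP1 replicate 2, and none passed over all genes in edgeR (3 rose when adjusted over the list alone).

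Nitrogen and remaining lists of the RNAi line held few passing loci. In the fixed nitrogen list 1 of 7 rose, LOC_Os04g43070 (AMT1;1, an ammonium transporter), from 75.3 ± 23.9 to 339.5 ± 132 CPM. In the extended list 2 of 11 rose, AMT1;1 and LOC_Os03g12290 (GLN1;2), and 2 fell, NIA1 (LOC_Os08g36480) and GLN1;1 (LOC_Os02g50240). The call was lost in 8 of 21 alternatives for AMT1;1 and for GLN1;2 and in 9 for NIA1. Of 5 phenylpropanoid loci 1 rose, LOC_Os08g34790 (4CL5), from 16.4 ± 5.34 to 75.2 ± 31.3 CPM, and 4CL3 (LOC_Os02g08100) fell. APX1 (LOC_Os03g17690) was the 1 antioxidant locus of 7 that rose (estimated correlation, camera adjusted p = 0.454). Of 6 clock loci 2 fell, LOC_Os09g36220 (PRR95) and LOC_Os02g40510 (PRR1), while LOC_Os08g06110 (LHY) and LOC_Os01g08700 (GI) changed by 0.00 ± 0.17 and 0.27 ± 0.20 in log2 (edgeR adjusted p = 0.992 and 0.371).

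Across all genes, 3934 passed in the RNAi line (2223 higher, 1711 lower under PEP1), of which 2361 changed at least 2-fold. LOC_Os12g38040 rose from 0.0186 ± 0.0323 to 14.7 ± 11.3 CPM and LOC_Os07g42040 was at least 64.2-fold higher (a call lost in 9 of 21 alternatives). Novel00992 fell from 102 ± 68.8 to 0.101 ± 0.0571 CPM and LOC_Os05g25550 was at least 42.9-fold lower. The count of passing genes was 1812 without RNAi ethanol replicate 1, 2311 without ethanol replicate 2, 1293 without ethanol replicate 3, 1475 without PEP1 replicate 1 and 1703 without PEP1 replicate 2. Without the 3 libraries that stood apart it was 2339.

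Both genotypes shared much of the response. In the same direction, 519 genes rose and 492 fell in both, against 56.4 and 45.4 for independent lists of those sizes, and 1 gene went opposite ways. These comparisons share no library. Of the wild type's passing genes 97.4% had the same sign in the RNAi line, and 1011 of the 1330 also passed there in that direction. Of the RNAi line's passing genes 96.0% had the same sign in the wild type. Across genes, which are not independent replicates, the log2 changes had a correlation of 0.72. The shared count was 2199 without wild type ethanol replicate 1, 671 without ethanol replicate 2, 577 without ethanol replicate 3, 477 without wild type PEP1 replicate 1, 499 without PEP1 replicate 3, 553 without RNAi ethanol replicate 3 and 594 without RNAi PEP1 replicate 1.

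**Figure D4:**
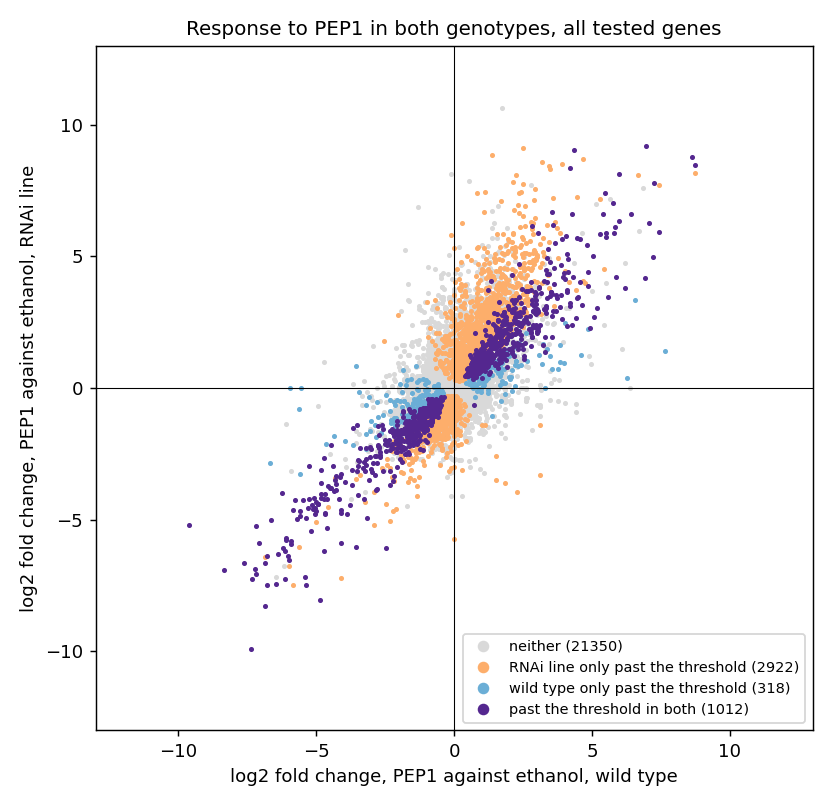
Log2 change with PEP1 in the wild type (horizontal axis) and in the RNAi line (vertical axis) for the 25602 tested genes, 1 point per gene, coloured by where the gene passed. Of them 1012 passed in both genotypes, 318 in the wild type alone and 2922 in the RNAi line alone. Passing in 1 genotype alone is not a test of a difference between the genotypes.

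The third comparison set the RNAi line against the wild type under ethanol. LOC_Os04g57720 (RR6, a cytokinin response regulator) was lower in the RNAi line, at 8.90 ± 0.583 against 36.0 ± 8.25 CPM, and LOC_Os02g57720 (PIP1-3, an aquaporin) was lower, at 1392 ± 188 against 2673 ± 139 CPM (n = 3 each). The auxin response genes LOC_Os06g07040 (IAA20) and LOC_Os02g56120 (IAA9) were higher, at 13.3 ± 0.593 against 4.16 ± 0.548 CPM and at 5.13 ± 0.643 against 1.84 ± 0.415 CPM. Loci with reads in 1 genotype only, described below, lie near PIP1-3 (such as LOC_Os02g57910) and IAA20 (LOC_Os06g07180). No such locus lies as near RR6 or IAA9 by locus number. Nearness was judged without a set cut-off and is given without the share of all genes lying as near, so it decides nothing. What caused the differences between the genotypes was not tested. NIA1 (LOC_Os08g36480), OPR1 (LOC_Os06g11290) and 4CL4 (LOC_Os06g44620) were lower, and SPX5 (LOC_Os03g29250) was higher, but these calls were lost in 10, 14, 13 and 9 of 21 alternatives, in that order, and IAA9's in 8. None of the 12 fixed iron loci passed in edgeR (0 when adjusted over the list alone, median log2 difference 0.01), and no list passed in camera, where the lowest adjusted p was 0.172.

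In total 971 genes differed between the genotypes under ethanol (553 higher and 418 lower in the RNAi line). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.00286 for RR6 (LOC_Os04g57720, log2 difference -2.01 ± 0.30, SE) and 0.00346 for IAA20 (LOC_Os06g07040, 1.68 ± 0.26). The largest differences were in features without a read in 1 group. LOC_Os11g34820 was at least 1784-fold and LOC_Os11g34810 at least 1361.5-fold higher in the RNAi line, and Novel00347 was at least 2872-fold and LOC_Os10g29650 at least 2676.5-fold lower. The count of passing genes was 611 without RNAi ethanol replicate 3.

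The fourth comparison set the genotypes against each other under PEP1. WRKY71 (LOC_Os02g08440) was higher in the RNAi line, at 125 ± 27.0 against 42.1 ± 2.12 CPM (n = 3 each), and AOS1 (LOC_Os03g55800) was higher, at 58.7 ± 6.56 against 30.5 ± 3.31 CPM. TIFY11D (LOC_Os10g25290) and LOC_Os03g51740 (ACS1, an enzyme of ethylene synthesis) were higher too, and PIP1-3 (LOC_Os02g57720) and LOC_Os01g72330 (RR4, a cytokinin response regulator) were lower, but these calls were lost in 13, 11, 11 and 12 of 21 alternatives, in that order. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment WRKY71 differed by 1.57 ± 0.23 on the log2 scale (SE, adjusted p = 0.00234) and AOS1 by 0.95 ± 0.17 (adjusted p = 0.0122). Camera called the jasmonate list up and the cellulose synthase list down (adjusted p = 0.0459 for each), and both calls were lost with an estimated correlation (adjusted p = 0.970).

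In total 679 genes differed under PEP1 (388 higher, 291 lower in the RNAi line). LOC_Os08g14195 was at least 1097-fold and LOC_Os10g04674 at least 830.5-fold higher, and Novel00347 was at least 4847-fold and LOC_Os06g21820 at least 2968-fold lower. The count of passing genes was 449 without wild type PEP1 replicate 1. Under both treatments 290 genes were higher and 230 lower in the RNAi line, against 8.38 and 4.75 for independent lists, and 0 went opposite ways in edgeR.

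Features with reads in 1 genotype only made up part of these differences. Counting a feature as without reads at 2 counts or fewer in each library, and as present at 1 CPM or more in each library, 76 features had reads in the wild type only and 81 in the RNAi line only, among them 63 and 59 loci with a LOC_Os ID. LOC_Os10g04674 had 0 CPM in wild type ethanol and 23.0 ± 3.29 CPM in RNAi ethanol, and Novel00347 had 163 ± 10.4 and 0 CPM. By treatment, 2 features had reads under ethanol only and 6 under PEP1 only. Of the 122 loci, 30 lie on chromosome 11 and 18 on chromosome 12, together 39.3% against 11.1% of eligible loci. All 157 features passed in both comparisons of the genotypes, which their definition on the same libraries made nearly certain. They were 16.2% of the passing genes under ethanol and 23.1% under PEP1.

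**Figure D5:**
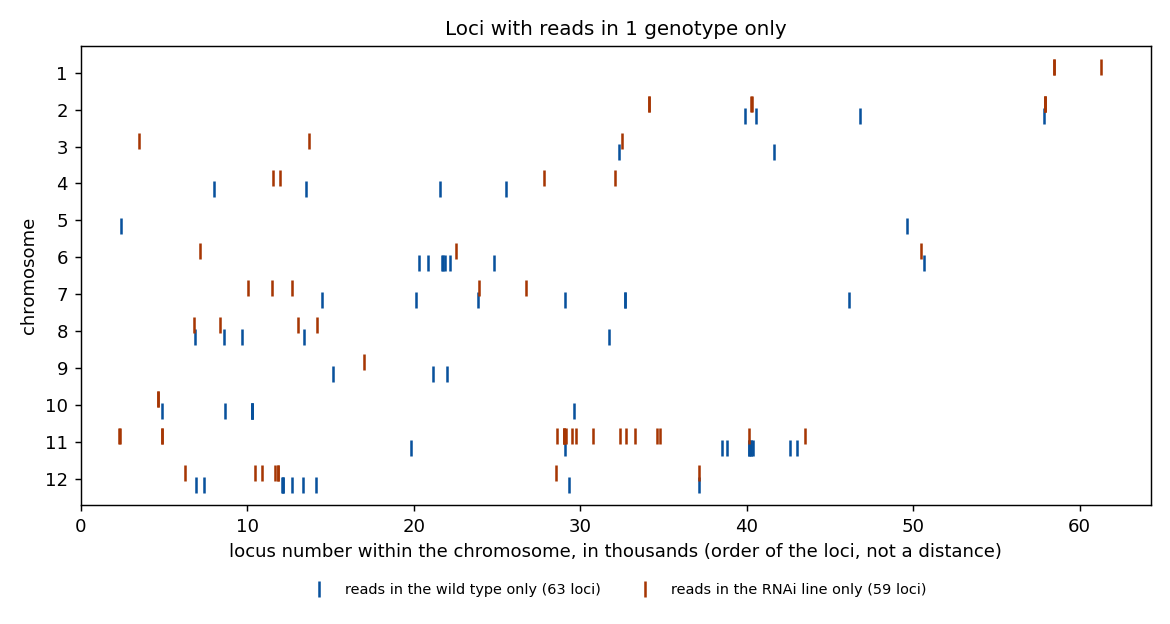
Positions by chromosome and locus number of the 63 loci with reads in the wild type only and the 59 with reads in the RNAi line only. Of the 122 loci, 30 lie on chromosome 11 and 18 on chromosome 12.

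A reversal was also tested, in which genes that differed between the genotypes under ethanol changed the opposite way with PEP1 in the RNAi line. It was found in 199 genes. Of these, 106 were higher in the RNAi line and fell with PEP1, and 93 were lower and rose, among them OPR1 (LOC_Os06g11290), whose genotype difference under ethanol was lost in 14 of 21 alternatives. Independent lists gave 37.0 and 36.3, and 44 genes changed the same way. The same RNAi ethanol libraries enter both comparisons. In 20 simulations of unchanged genes, drawn independently of each other, the mean covariance of the log2 changes was -0.101 against -0.371 observed. Their mean correlation was -0.50 in the simulations against -0.26 observed, so on that scale the simulated relation was the stronger. The simulations therefore do not show a reversal beyond the shared libraries. With different RNAi ethanol libraries in each comparison, the covariance of the log2 CPM differences ranged from -0.281 to 0.0190 over 6 divisions (mean -0.153), against -0.222 with all 3 in both. The count was 302 without wild type ethanol replicate 2, 109 without ethanol replicate 3, 117, 89 and 49 without RNAi ethanol replicates 1, 2 and 3, and 93 and 129 without RNAi PEP1 replicates 1 and 2.

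The last comparison tested whether the response to PEP1 differed between the genotypes. LOC_Os12g13340 was the only gene that passed. It had 1827 ± 87.5 CPM in wild type ethanol and 36.8 ± 12.6 CPM in wild type PEP1, against 12.4 ± 2.64 and 7.17 ± 2.58 CPM in the RNAi line (n = 3 each). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment its interaction was 4.84 ± 0.43 on the log2 scale (SE, adjusted p = 0.00684). At an unadjusted p below 0.05 there were 1353 genes, DESeq2 called 95 and limma-voom 352. Without wild type ethanol replicate 1 the edgeR count was 6, without the 3 libraries that stood apart it was 4, with the replicate number as a block it was 2, and it was 0 without wild type PEP1 replicate 3, RNAi ethanol replicate 2 or RNAi ethanol replicate 3.

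The extended jasmonate list differed between the genotypes in its response by camera. Only LOC_Os03g12500 (AOS2) in it was written before the data were examined, so the list is not independent evidence. All 11 loci had a positive interaction, with a median of 1.08 on the log2 scale. None passed over all genes in edgeR and 5 rose when adjusted over the list alone. Camera's adjusted p with an estimated correlation was 0.0255. LOC_Os03g08310 (TIFY11A) and LOC_Os03g08320 (TIFY11C), JAZ repressors, had interactions of 2.01 ± 0.54 and 1.73 ± 0.65 (SE). The 3 shoot markers moved the same way, with a median interaction of 4.22, and none passed in edgeR (0 when adjusted over the list alone); CAB2R (LOC_Os01g41710) changed by -0.42 ± 1.34 in the wild type and by 3.86 ± 1.51 in the RNAi line. WRKY71 (LOC_Os02g08440) had one of 1.35 ± 0.31 (edgeR adjusted p = 0.467). In camera the fixed iron and nitrogen lists were up and the fixed root development list down (adjusted p = 0.00192, 0.0121 and 0.0140), and all of these calls were lost with an estimated correlation (adjusted p = 0.412).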

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

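The results in this part drew attention because the response to PEP1 differed between the genotypes by a test of the difference itself. The tests of off-target silencing and of neighbouring loci were chosen only after the results were seen, and so were the fits that leave out libraries from the jasmonate list.

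LOC_Os12g13340 was the only gene past the threshold of the interaction in edgeR, with 4.84 on the log2 scale, and under ethanol it already stood at 1827 ± 87.5 CPM in the wild type against 12.4 ± 2.64 CPM in the RNAi line (n = 3 each). With 10 of 100 shuffles of the treatments within the genotypes, the real one included, giving as many genes (highest other count 2), chance was not excluded for this count. Loci near it differed between the genotypes too. LOC_Os12g13350 had 145 ± 59.2 CPM in wild type ethanol and 0 CPM in both RNAi groups, LOC_Os12g13674 had 716 ± 245 and 0.106 ± 0.103 CPM under ethanol, and LOC_Os12g13290 had 284 ± 119 and 3.78 ± 0.381 CPM. With PEP1 in the wild type, LOC_Os12g13350 fell by 5.95 and LOC_Os12g13674 by 1.41 on the log2 scale (edgeR adjusted p = 0.00173 and 0.0443). LOC_Os12g13290 did not pass there (edgeR adjusted p = 0.565). Of 19 other tested loci in the surrounding window, 3 differed between the genotypes under ethanol, against 971 of all 25602 tested genes.

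The features with reads in 1 genotype only were weighed next to it. No other of the 462 splits of the 12 libraries into equal groups gave more than 8 such features, against 157 by genotype. Off-target silencing by the construct stays open for the 76 features with reads in the wild type only, and for the 81 with reads in the RNAi line only as an indirect gain, which was not tested. A candidate explanation is that the RNAi line and the wild type differ in segments of the genome: of the 122 loci, 23 pairs were direct neighbours along the locus order, against a median of 1 and a maximum of 8 in 10000 shuffles (permutation p = 1e-04, the smallest they can give), and 4 of the 23 pairs joined loci of opposite kinds. This remains a hypothesis found and tested on the same data, and lower OsPEP1 in the RNAi line stays among the open explanations, untested.

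For the jasmonate list, the camera p-values below are unadjusted and for that list alone. They do not show whether its adjusted call would hold with libraries left out. With loci added later, this list had a median interaction of 1.08. It was 1.18 without RNAi PEP1 replicate 2 (camera p = 0.00164 with an estimated correlation), 0.93 without wild type ethanol replicate 1 (p = 0.00260), and 0.87 without the 3 libraries that stood apart (p = 0.00845), against p = 0.00121 with all 12 libraries, and 11 of 11 loci were positive in each. The 3 shoot markers had a median interaction of 4.22 with all libraries and of 3.81 without those 3, and none passed in either, so a difference in tissue between the samples was not excluded. The WRKY list had a median interaction of 1.07, and of 0.47 without the 3 libraries (camera adjusted p = 0.215 with an estimated correlation).

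The fixed iron list had a median interaction of 0.50, the smaller fall being in the RNAi line, the fixed nitrogen list 2.28 and the fixed root development list -0.60, none of which was called with an estimated correlation (camera adjusted p = 0.412 for each). The extended nitrogen list had 1.86, and 0.30 without the 3 libraries that stood apart, the nitrate transport genes being high in wild type ethanol replicate 1, which is among them. The phenylpropanoid list had 0.32, the extended root development list -0.54 (-0.23 without the 3 libraries) and the early auxin response list -0.22, with camera adjusted p of 0.692, 0.692, 0.756 and 0.756 for these 4 extended lists, in that order, with an estimated correlation.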

How the results depend on the processing

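The alternative without the 3 libraries that stood apart was chosen after seeing the data, and the others were planned. Called values of named genes kept their direction wherever they were called, but many did not keep their side of the threshold. Of 120 called values of named genes, 61 were called in every alternative, 59 lost the call in at least 1, and 0 changed sign while called. The cause was not tested for the shifts given here, except where fewer libraries or a minimum change explain them.

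For PEP1 in the wild type, PEP1 in the RNAi line, the genotypes under ethanol, the genotypes under PEP1, the interaction, the shared response and the reversal, in this order, DESeq2 called 2577, 6291, 1699, 1044, 95, 1901 and 507 genes and limma-voom 7427, 13766, 3454, 2249, 352, 5981 and 1622. With only the groups compared in the fit, the wild type gave 535 genes, the genotypes under ethanol 596, the shared response 422 and the reversal 114. A minimum change of 2-fold left 2361 genes in the RNAi line. Without the 3 libraries that stood apart the counts were 2882 for PEP1 in the wild type, 2339 for PEP1 in the RNAi line, 639 for the genotypes under ethanol, 4 for the interaction, 1542 shared and 85 reversed. In that fit KSL7 (LOC_Os02g36140) went to -2.86 between the genotypes under ethanol (edgeR adjusted p = 0.0201), from 2.19 with all libraries.

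Leaving out each library in turn gave 571 to 2942 genes for PEP1 in the wild type, 1293 to 5604 for PEP1 in the RNAi line, 611 to 1046 and 449 to 757 for the genotypes under ethanol and PEP1, 0 to 6 for the interaction, 477 to 2199 shared and 49 to 302 reversed.

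The replicate numbers were not shown to pair the libraries. Of 18 pairs of same-numbered libraries 9 had a correlation over 0.1 (range -0.49 to 0.60), and in 11 of 36 checks a library correlated best with its own number. With the replicate number as a block 2 genes passed in the interaction, the fixed lists gave 1 call and the extended lists 4 between the genotypes under PEP1, and no other count moved by over 1.5 times.

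With library totals alone the wild type calls were 785 higher and 583 lower, against 650 and 680. For lists, camera with an estimated correlation called 0 fixed lists in the interaction, and of the extended lists 1 for PEP1 in the wild type, 0 in the RNAi line, 0 between the genotypes under PEP1 and 1 in the interaction. Fry called 0 fixed lists in the interaction, and of the extended lists 5 in the wild type, 0 between the genotypes under PEP1 and 1 in the interaction. At this depth a count of 0 in a library allows up to 0.195 CPM.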

Other observations

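All tests of the iron genes, of exchanged labels and of divided RNAi ethanol libraries in this part were chosen only after the results were seen; the splits of the samples were planned.

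Further lists gave few passing genes for PEP1. Of 13 cytokinin loci 1 rose in the wild type, LOC_Os10g34230 (CKX3, a cytokinin oxidase), from 21.1 ± 5.07 to 39.3 ± 4.50 CPM, and 1 rose and 2 fell in the RNAi line; without the 3 libraries that stood apart 2 rose and 3 fell in the wild type. Of 3 gibberellin loci 1 fell in the wild type, LOC_Os01g66100 (GA20OX2, gibberellin 20-oxidase), from 8.18 ± 0.866 to 2.15 ± 1.15 CPM, and 2 fell in the RNAi line, GA20OX2 (6.01 ± 0.615 to 1.15 ± 0.380 CPM) and LOC_Os05g33730 (GID1, the gibberellin receptor). GID1's call was lost in 13 of 21 alternatives, and without the 3 libraries 1 of the 3 loci fell in the RNAi line. Of 3 ethylene synthesis loci LOC_Os09g27820 (ACO1) fell in the wild type, from 2.54 ± 0.731 to 0.424 ± 0.121 CPM, and LOC_Os03g51740 (ACS1) rose in the RNAi line, from 2.67 ± 0.850 to 6.24 ± 0.415 CPM. Of 21 early auxin response loci 0 passed in the wild type in edgeR (0 adjusted over the list alone), and 2 rose and 1 fell in the RNAi line, where 0 passed in edgeR without the 3 libraries.

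Of 7 hypoxia loci 1 rose in each genotype, and of 5 abscisic acid loci and 11 expansins 1 rose in the RNAi line. Of 3 pathogenesis-related loci in the extended list 1 rose in the RNAi line, and none of the 3 tested fixed ones passed in either genotype (2 rose in the RNAi line when adjusted over the list alone). No locus passed in edgeR for PEP1 in either genotype in the lists of heat shock (6 loci), auxin transport (7), cell division (6), DNA replication (3), root development (6 fixed, 7 extended), root hair (2) and seed storage (2). Adjusted over the list alone the count in these lists was 0 as well, except for 1 fixed root hair locus that fell in the RNAi line. In the wild type 0 of 6 clock loci (1 fell when adjusted over the list alone) and 0 of 3 shoot markers passed in edgeR. The shoot marker CAB2R (LOC_Os01g41710) had 113 CPM in wild type ethanol replicate 2, against 18.9 and 6.17 CPM in the other libraries of that group.

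For the fall of the iron genes in both genotypes, scaling between libraries was argued against, since a wrong factor for a library moves all genes alike and leaves their order. Ordered by log2 change, the 12 fixed loci had a median percentile of 0.316 in the wild type and 0.363 in the RNAi line, counted from the largest fall among all tested genes; the highest single loci lay at 20.6 and 73.9. A hypothesis is that PEP1 itself lowers these genes. If the OsPEP1 of the plant did the same, less of it in the RNAi line might raise them under ethanol, but the median difference there was 0.007375; this decides nothing, since the level of OsPEP1 in the RNAi line was not analysed here. A difference in medium or handling between the treatments cannot be told apart from PEP1, because 10 of the 12 loci fell in both genotypes and the design varies the treatment in 1 way only.

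The counts for PEP1 in the wild type came with a structure of the samples. Of the 10 splits of its 6 libraries 2 gave as many genes as the real one (1330); the other, wild type ethanol replicate 1 with PEP1 replicates 1 and 3 against the rest, gave 1852, and 7 genes passed in both. Exchanged labels between ethanol replicate 1 and PEP1 replicate 2 were argued against: the iron loci were higher in the first by a median of 5.81 on the log2 scale, and all 12 put ethanol replicate 1 above every PEP1 library and PEP1 replicate 2 below every ethanol library. The mean shift of the genes that passed in the RNAi line, signed by their direction there, was -0.16, -0.63 and -0.49 in wild type ethanol and 0.49, 0.24 and 0.62 in wild type PEP1, in log2 units around the mean of all 12 libraries. What sets these libraries apart stays open, and no biological explanation was tested.

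With 10 splits no share below 0.05 can be reached in comparisons of 3 libraries with 3. In 1 of 10 splits, the real one, as many genes passed for PEP1 in the RNAi line (3934, highest other 1), for the genotypes under ethanol (971, highest other 1) and for the genotypes under PEP1 (679, highest other 1). For the shared response, 1 of 100 shuffles of the treatments within the genotypes, the real one included, gave as many genes (1011, highest other 1). That is the smallest share that 100 can give. It argues only against such a count with no difference at all between the treatments. It also takes the libraries as independent, which the labels do not state. For the reversal 1 of 60, the real one, did (199, highest other 1), but those shuffles also remove the effects of genotype and PEP1. With the shared RNAi ethanol libraries divided between the comparisons, 1 of 6 divisions had a covariance that was not negative (0.0190) and the others ranged from -0.281 to -0.0771, so whether the reversal goes beyond the shared libraries stays open.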
